A study of Mus musculus with 6 samples.

How the data were processed

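Poly-A selected, strand-marking libraries were made from 50 ng of total RNA per spleen piece on an automated system, per the labels' protocols, from 3 mutant and 3 control animals. The authors deposited a table of whole-number counts per Ensembl gene, with no normalization. STAR 2.5.3a, the builds mm10 and GRCm38, and limma are named without roles, per the submitters' processing notes. The gene annotation release, the strand setting of the counting, the handling of reads that map to several places and any filter are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies, such as the haemoglobin genes, may therefore be assigned in ways that cannot be traced from the counts.

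The table held 31771 gene identifiers, of which 31669 matched a symbol and 102 did not, and 14 identifiers shared their symbol with another. Coordinates were taken from the GENCODE M21 annotation of GRCm38 by identifier. Libraries held 72902118 to 79258116 counts. Each column name matched the title of 1 sample, and 0 columns were left without a sample. Groups were taken from the genotype label. Replicate numbers follow accession order and only name the animals, so no mutant was paired with a control. The labels give no batch, age or litter. No pair of libraries agreed within sampling noise: the chi-square per gene was 22.0 to 86.2 between controls and 738 to 1492 between mutants, over genes with a summed count of at least 20. Planned shares of counts covered haemoglobin genes, immunoglobulin segments and the 10 most abundant genes. The planned mitochondrial share was not analysed here, because no matched symbol starts with mt-.

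The main test was edgeR 4.0.16 in R 4.3.3 with TMM factors, the package's expression filter by group, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05, with no covariate. It kept 19573 genes. CPM (counts scaled to a common library total) were computed from the deposited counts without TMM factors, and log2 CPM with TMM factors and a prior count of 2 was used for lists. The SE is the fitted log2 fold change divided by the square root of the F statistic. Before the data were examined, 23 gene lists with 383 genes were fixed, of which 379 genes were found. The 22 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated for each list. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.210. The fry test, which asks only whether a list moves on balance in one direction, passed 5 lists: B cell, T cell, plasma cell, splenic stroma and cell cycle. Shares were compared by exact 2-sided permutation tests, which cannot go below p = 0.1 here. The counting interval of a ratio is exact at 95% and covers counting error only.

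Genes were named by a rule fixed beforehand. It takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with an average log2 CPM of at least 2 and no overlap between groups. Xist, Y-linked genes, immunoglobulin and T-cell receptor segments, and predicted genes were left out of that part. It adds the 2 members with the smallest p from each list with a passing member, the most abundant member of each other list, and Pi4ka and Cdh5. Identifiers without a symbol were left out as well, a detail added after the data were seen. Ifi202b was named outside this rule. Xist, Ddx3y, Lrg1, Mt1, Cd72, Cxcl13, Des, Myh11, Tlx1, Col1a1, Hbb-bs, Klf1, Gata1, Mpo, Prtn3, Ms4a3, Cebpe, Padi4, Camp and Egfl7 were named after their values were seen, as were the genes of the closing section that the rule does not name.

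The procedure was tested on simulated counts with the means and library sizes of these libraries, in which 200 genes were changed in the mutants. Both groups were given the same joint dispersion per gene, unlike the real groups, of which the mutants varied more. Over 19056 genes edgeR found 0% of the 2-fold changes, 10.4% of the 4-fold and 60.6% of the 16-fold changes, with 9 false calls and 0 calls when nothing was changed. DESeq2 found 7.46%, 49.3% and 89.4%, with 114 false calls, 1 call of the wrong sign and 72 calls when nothing was changed. In the real libraries edgeR also called genes that changed by less than 2-fold. Alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, other expression filters, haemoglobin or immunoglobulin genes left out, a test against a 2-fold change, other list tests, and each library left out in turn. A variance for each group and a fit without X and Y genes were added after the data were seen.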

Results

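RNA from pieces of spleen was sequenced from 6 mice labelled as strain C57BL/6, of which 3 were mutant and 3 were wild-type controls. The mutant genotype combined Cre recombinase under the VE-cadherin promoter, a Sleeping Beauty (SB) transposase and the onc2 transposon. Sleeping Beauty is a DNA transposon that its transposase moves to new sites in the genome, where the onc2 version can activate or break genes. VE-cadherin, encoded by Cdh5, is an adhesion molecule of endothelium, and Cre under its promoter is also active in blood cells that arise from embryonic endothelium. The series asked how the cell composition of the spleen differed, within a screen that led to the lipid kinase gene Pi4ka. Each library held between 72902118 and 79258116 gene counts. Between 24607 and 25804 genes had a count. Levels are given as CPM, a gene's counts scaled to a common library total, as mean ± SD over the animals of a group (n = 3), and fold changes as log2 of mutant over control ± SE, with positions on GRCm38. Xist, the transcript of the inactive X chromosome, stood at 1513 CPM in mutant 1 and 580 CPM in mutant 2, against 0.586 CPM in mutant 3 and 0.423 to 0.663 CPM in the controls. The Y-linked gene Ddx3y was at 60.4 CPM in mutant 3 and 55.0 to 62.7 CPM in the controls, and at 0.0412 and 0.0269 CPM in mutants 1 and 2, so the groups differed in sex as well as genotype. Reads of antisense or overlapping genes and of near-identical paralogs, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt or the copies of Ccl21a, are uncertain because the strand setting and the handling of shared reads are not stated.

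B-cell genes fell in the mutant spleens (17 of the 18 tested, list median log2 fold change -6.67), as did 9 of 20 T-cell genes and 6 of 16 splenic stroma genes, including the chemokine genes Ccl21a, Ccl19 and Cxcl13. In the cell cycle list 18 of 24 genes rose. In the neutrophil list 7 of 26 genes rose, among them Ctsg and Mpo, and in the erythroid list 6 of 30, among them Tal1 and Tfr2, while haemoglobin genes did not pass. The camera calls of all 6 lists were lost with an estimated correlation (adjusted p = 0.210 for B cell, 0.784 for erythroid and 0.597 for the other 4, each with an estimated correlation). Myeloid and progenitor transcripts differed widely from one mutant animal to the next. Of 19573 genes tested, 995 rose and 1351 fell at an adjusted p under 0.05 by edgeR's quasi-likelihood test. Among them, 767 rose and 1253 fell by 2-fold or more, and 56 rose and 516 fell by 16-fold or more. All 995 and all 1351 had mutant libraries that did not overlap the controls, an arrangement that chance gives 10% of genes. The mutants varied far more than the controls, with a biological coefficient of variation of 72.7% against 17.1%. Without control 1, 2 or 3, the calls dropped to 6, 4 and 8 genes higher and 130, 119 and 128 lower. At an unadjusted p under 0.05 edgeR then gave 1761 to 1933 genes higher and 2106 to 2178 lower, and 37, 38 and 37 of the 60 named genes no longer passed. The calls rose to 1780 higher without mutant 1, and to 2794 higher and 3137 lower without mutant 2. In the main test and with each of the 6 libraries left out in turn, 3 genes rose (En2, Lrg1 and Mt1) and 118 fell, of which 13 belonged to the B-cell list and 17 were immunoglobulin segments.

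**Figure D1:**
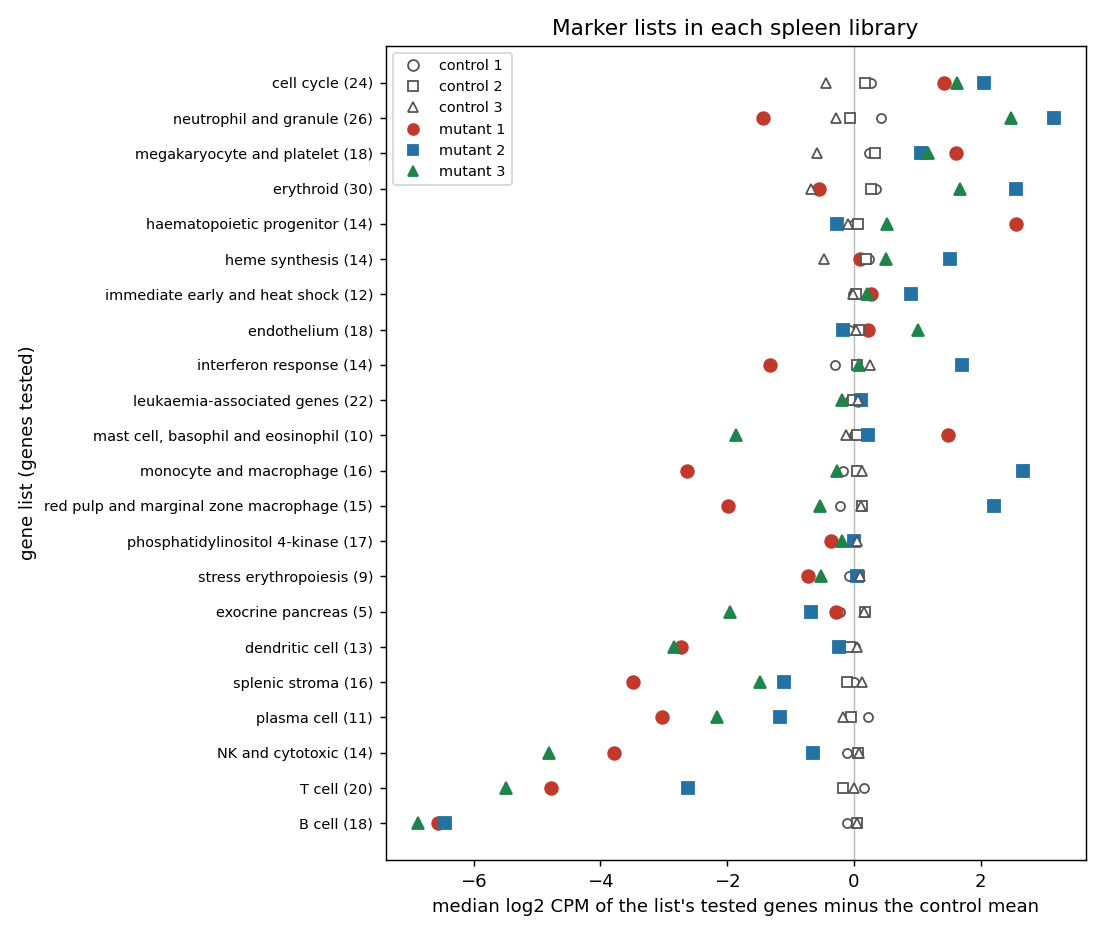
Median log2 CPM of the tested genes of each list in each library, minus the control mean (x axis), for the 22 lists tested (y axis, number of tested genes in brackets). Open symbols are the 3 controls and filled symbols the 3 mutants; the B-cell list lies at -6.56, -6.45 and -6.89 in mutants 1, 2 and 3, whereas the neutrophil list lies at -1.43 in mutant 1 and at 3.16 and 2.48 in mutants 2 and 3.

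The B-cell list fell further than any other list tested. Of its 18 tested members 17 fell, also 17 adjusted over the list alone, with a median log2 fold change of -6.67 (adjusted p = 4.06e-20 by camera with a preset correlation). With an estimated correlation that call was lost (adjusted p = 0.210 with an estimated correlation), and by fry the adjusted p was 6.03e-05. Fcmr, the Fc receptor for immunoglobulin M (ENSMUSG00000042474, chromosome 1, 130865669 to 130880791), fell from 662 ± 66.1 to 3.97 ± 0.320 CPM (log2 -7.36 ± 0.25, adjusted p = 0.000378). Ebf1, a transcription factor that B-cell identity needs (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), fell from 177 ± 18.1 to 1.83 ± 0.272 CPM (log2 -6.59 ± 0.25, adjusted p = 0.000479). Fcer2a, Cr2 and Ms4a1, which encode the mature B-cell surface proteins CD23, CD21 and CD20, fell by 8.13 ± 0.39, 8.07 ± 0.33 and 7.26 ± 0.34 on the log2 scale. The member that did not pass was Cd72, at 186 ± 7.45 CPM in controls and 5.60, 99.6 and 7.05 CPM in mutants 1, 2 and 3 (adjusted p = 0.247). Without any single control 13 members still passed, and without mutant 1, 2 or 3 the number was 17, 18 and 16.

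Of 232 immunoglobulin segments tested, 129 fell and the others did not pass. Their share of all counts was 0.372 ± 0.343% in mutants and 2.77 ± 0.228% in controls (exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allows, and 0.1 after adjustment over 3 shares). The 10 most abundant genes of each library took 6.59 ± 2.63% of counts in mutants and 13.8 ± 1.98% in controls, with the same exact permutation p. The plasma cell list fell (adjusted p = 0.00169, and adjusted p = 0.597 with an estimated correlation), with 5 of 11 members lower and 6 adjusted over the list alone. Mzb1, a chaperone of antibody assembly, fell from 162 ± 11.2 to 8.16 ± 6.73 CPM (log2 -4.26 ± 0.67, adjusted p = 0.0175). Txndc5, a disulfide isomerase of the secretory pathway, fell from 284 ± 14.6 to 120.4 ± 15.8 CPM (log2 -1.23 ± 0.18, adjusted p = 0.0152). The 5 plasma cell genes no longer passed without any single control, and without mutant 1, 2 or 3 the number lower was 3, 8 and 2.

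The T-cell list fell with a median log2 fold change of -3.70 (adjusted p = 9.51e-10, and adjusted p = 0.597 with an estimated correlation). Of 20 members 9 fell, and 17 fell adjusted over the list alone. Ccr7, the receptor that brings lymphocytes into T-cell zones (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), fell from 127 ± 3.02 to 2.44 ± 0.248 CPM (log2 -5.69 ± 0.17, adjusted p = 0.000378). Lef1, a transcription factor of naive T cells, fell from 90.9 ± 6.67 to 1.29 ± 0.448 CPM (log2 -6.12 ± 0.38, adjusted p = 0.00153). The list median was -4.79 in mutant 1, -2.62 in mutant 2 and -5.49 in mutant 3. Without any single control 3 members passed, and without mutant 1, 2 or 3 the number was 4, 18 and 7. DESeq2 and limma-voom each called 17 members lower. Of 63 tested genes with symbols that begin like those of T-cell receptor segments, 19 fell and 1 rose. That choice by symbol would also take in Tradd, which is not a segment, and the gene that rose was not identified here.

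The natural killer and cytotoxic list fell (median log2 -1.68, adjusted p = 0.00169, and adjusted p = 0.597 with an estimated correlation), with 1 of 14 members passing, also 1 adjusted over the list alone. That member was Klri2, a killer-cell receptor, with 658 counts over the 3 controls and 2 counts over the 3 mutants, a ratio of 319 with a 95% exact counting interval of 87.9 to 2639 (adjusted p = 0.0113). Tbx21, a regulator of cytotoxic cells, was at 14.9 ± 2.09 CPM in controls and 0.329, 2.47 and 0.195 CPM in mutants 1, 2 and 3 (adjusted p = 0.0699). The dendritic cell list fell (median log2 -1.22, adjusted p = 0.00533, and adjusted p = 0.597 with an estimated correlation), with 2 of 13 members lower and 4 adjusted over the list alone. These were Ccr9, a chemokine receptor of plasmacytoid dendritic cells (log2 -3.08 ± 0.40, adjusted p = 0.0109), and Clec9a, a receptor of cross-presenting dendritic cells (log2 -2.23 ± 0.46, adjusted p = 0.0326). The dendritic list median was -0.23 in mutant 2, against -2.73 and -2.83 in mutants 1 and 3. Klri2, Ccr9 and Clec9a no longer passed without any single control, whereas without mutant 2 the members that fell numbered 8 in the natural killer list and 10 in the dendritic list. By limma-voom with sample weights 8 members fell in each of these lists, and by DESeq2 3 in the natural killer list and 4 in the dendritic list, where 1 rose.

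The splenic stroma list fell (median log2 -1.81, adjusted p = 0.000204, and adjusted p = 0.597 with an estimated correlation), with 6 of 16 members lower and 8 adjusted over the list alone. Ccl21a, a chemokine made by stromal cells of T-cell zones (ENSMUSG00000094686, chromosome 4, 42772860 to 42773993), fell from 312 ± 38.6 to 7.26 ± 1.28 CPM (log2 -5.41 ± 0.26, adjusted p = 0.000704). Ccl19, a chemokine of the same receptor, fell from 56.9 ± 8.75 to 0.902 ± 0.705 CPM (log2 -5.93 ± 0.80, adjusted p = 0.0127). The other 4 were Cxcl13, the chemokine of B-cell follicles, the muscle genes Des and Myh11, and Tlx1, a transcription factor of spleen mesenchyme. The fibroblast collagen gene Col1a1 was at 75.1 ± 7.49 CPM in controls and 90.6 ± 62.2 CPM in mutants (adjusted p = 0.748). Of the 16 members, 1 fell without any single control, and 9 without mutant 2.

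**Figure D2:**
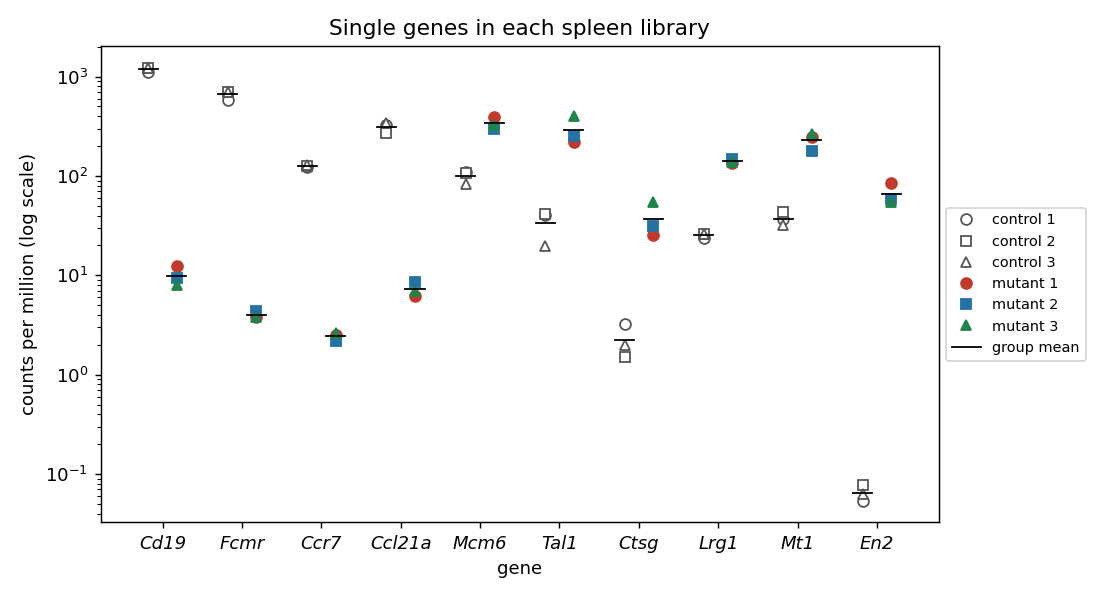
CPM (y axis, log scale) of 10 genes (x axis) in each library, with open symbols for the 3 controls, filled symbols for the 3 mutants and lines at the group means. Fcmr fell from 662 to 3.97 CPM on average and En2 rose from 0.0647 to 65.9 CPM. The 10 genes were taken from those past the threshold, none of which overlapped between mutants and controls.

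The cell cycle list rose in all 3 mutants, with medians of 1.43, 2.06 and 1.62 in mutants 1, 2 and 3 (adjusted p = 3.56e-13, and adjusted p = 0.597 with an estimated correlation). Of 24 members 18 rose, and all 24 rose adjusted over the list alone. Mcm6, part of the helicase that opens DNA for replication (ENSMUSG00000026355, chromosome 1, 128331590 to 128359664), rose from 100.1 ± 14.7 to 340.4 ± 48.9 CPM (log2 1.77 ± 0.21, adjusted p = 0.00909). Tyms, the thymidylate synthase of nucleotide supply, rose from 18.6 ± 5.05 to 86.1 ± 4.13 CPM (log2 2.21 ± 0.26, adjusted p = 0.00944). Without control 3, 1 member passed over all genes, and without control 1 or 2 the members no longer passed. With limma-voom and a variance for each group, 6 of the 24 rose.

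The erythroid list rose (median log2 1.85, adjusted p = 0.00295, and adjusted p = 0.784 with an estimated correlation), with 6 of 30 members higher and 10 adjusted over the list alone. Tal1, a transcription factor of early erythroid and megakaryocyte cells (ENSMUSG00000028717, chromosome 4, 115056426 to 115071755), rose from 33.9 ± 12.2 to 291 ± 98.1 CPM (log2 3.09 ± 0.40, adjusted p = 0.0117). Tfr2, a transferrin receptor of erythroid precursors, rose from 9.62 ± 3.06 to 105 ± 57.7 CPM (log2 3.43 ± 0.52, adjusted p = 0.0164). The 4 haemoglobin genes did not follow: their log2 fold changes lay between -2.66 and -1.64 with adjusted p between 0.234 and 0.360. Hbb-bs, an adult beta-globin gene, was at 53144 ± 12495 CPM in controls and at 2443, 29734 and 844 CPM in mutants 1, 2 and 3, respectively (adjusted p = 0.306). Haemoglobin genes took 2.05 ± 2.90% of all counts in mutants and 9.44 ± 2.15% in controls (exact 2-sided permutation p = 0.1, the smallest possible, and 0.1 after adjustment). The list median was -0.54 in mutant 1, 2.57 in mutant 2 and 1.67 in mutant 3. Without mutant 2 the list no longer passed (adjusted p = 0.257), with 4 members higher and 6 lower. The members that rose numbered 18 without mutant 1 and 3 without mutant 3, and the 6 no longer passed without any single control. Klf1 and Gata1, transcription factors of erythroid cells, did not pass (log2 2.11 ± 0.71 and 2.28 ± 0.67, adjusted p = 0.104 and 0.0796). By DESeq2 16 members rose, and by limma-voom 7 members were higher and 5 lower with sample weights, and 3 higher and 1 lower with a variance for each group.

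**Figure D3:**
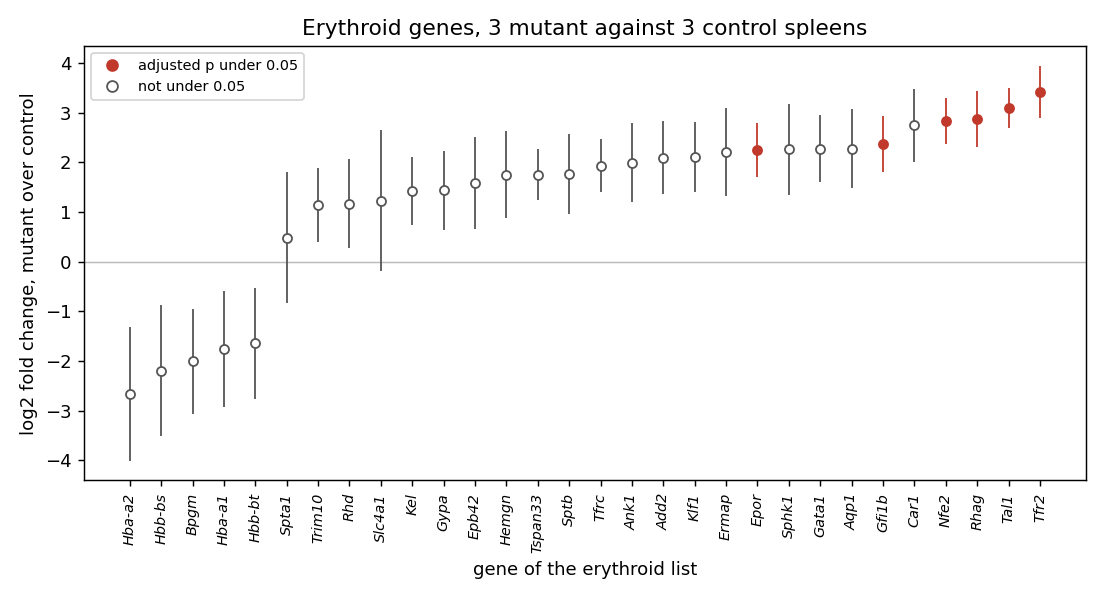
Log2 fold change, mutant over control (y axis), of the 30 tested genes of the erythroid list (x axis, sorted), with bars of 1 SE from edgeR and filled points for the 6 genes with an adjusted p under 0.05. The 4 adult haemoglobin genes lie between -2.66 and -1.64, while Tal1 and Tfr2 lie at 3.09 and 3.43.

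The heme synthesis list rose (median log2 0.80, adjusted p = 0.0327, and adjusted p = 0.784 with an estimated correlation), with 1 of 14 members passing, also 1 adjusted over the list alone. Alad, the second enzyme of heme synthesis, rose from 192 ± 48.8 to 769 ± 336 CPM (log2 2.03 ± 0.43, adjusted p = 0.0339). Cpox, a later enzyme of the pathway, was at 61.1 ± 14.2 and 284 ± 197 CPM (adjusted p = 0.0660). This list did not pass without control 3 (adjusted p = 0.0983), without mutant 2 (0.410), by limma-voom with sample weights (0.184) or with a variance for each group (0.0618), or by fry (0.393), and its adjusted p ranged from 0.00370 to 0.784 over all alternatives. Without any single control Alad no longer passed, while 3 members rose without mutant 1 and 2 fell without mutant 2, and by DESeq2 4 rose. The megakaryocyte and platelet list rose, with medians of 1.62, 1.07 and 1.17 in the 3 mutants (adjusted p = 0.00564, and adjusted p = 0.597 with an estimated correlation). Of 18 members 4 rose, and 7 rose adjusted over the list alone. Vwf, the clotting protein that carries platelets to vessel walls, rose from 56.6 ± 13.7 to 143 ± 42.2 CPM (log2 1.33 ± 0.28, adjusted p = 0.0349). Rab27b, a small GTPase of platelet granules, rose from 8.97 ± 2.86 to 76.3 ± 51.1 CPM (log2 3.06 ± 0.69, adjusted p = 0.0406). The 4 megakaryocyte genes no longer passed without any single control or without mutant 3, and 12 members rose by DESeq2 and 1 by limma-voom with a variance for each group.

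The neutrophil and granule list rose (median log2 2.69, adjusted p = 0.000544, and adjusted p = 0.597 with an estimated correlation), with 7 of 26 members higher, also 7 adjusted over the list alone. Ctsg, a protease of primary granules (ENSMUSG00000040314, chromosome 14, 56099881 to 56102574), rose from 2.24 ± 0.882 to 37.1 ± 15.3 CPM (log2 4.05 ± 0.45, adjusted p = 0.00841). Hp, which encodes haptoglobin, rose from 10.2 ± 0.633 to 62.9 ± 31.6 CPM (log2 2.63 ± 0.39, adjusted p = 0.0152). The other 5 were Mpo, Prtn3, Ms4a3, Cebpe and Padi4, of which Mpo and Prtn3 encode primary granule proteins and Ms4a3 marks granulocyte and monocyte precursors. The secondary granule gene Camp was at 29.2 ± 7.96 CPM in controls and at 2.39, 230.3 and 45.5 CPM in mutants 1, 2 and 3 (adjusted p = 0.417). Without mutant 2 the list no longer passed (adjusted p = 0.0740), and 1 member, Ctsg, rose without control 1. Without control 2 or 3 the 7 no longer passed, and without mutant 1 the number was 19, against 14 by DESeq2 with all libraries.

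The monocyte and macrophage list did not pass (median log2 1.36, adjusted p = 0.507), with medians of -2.63, 2.68 and -0.26 in mutants 1, 2 and 3. Its 1 passing member of 16, with 0 adjusted over the list alone, was F13a1, a clotting factor subunit of monocytes (log2 5.32 ± 1.14, adjusted p = 0.0359), at 7.69 ± 1.23 CPM in controls and 83.5, 724 and 68.4 CPM in the mutants. Cd14, a receptor for bacterial lipopolysaccharide, was at 10.2 ± 0.812 CPM in controls and 75.2 ± 103 CPM in mutants (adjusted p = 0.136). F13a1 no longer passed without any single control, and without mutant 1 the list passed as higher (adjusted p = 0.0255, over a range of 0.0255 to 0.976 among its alternatives). Without mutant 2, 3 members of the monocyte and macrophage list were lower. In the list of red pulp and marginal zone macrophages 0 of 15 members passed by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, though 2 were lower by limma-voom with sample weights. Its median log2 fold change was 0.92 while the set test pointed down (adjusted p = 0.988), and without mutant 2 it passed as lower with 3 members lower (adjusted p = 0.00817, over a range up to 0.997). C1qa, a complement subunit of macrophages, was at 143 ± 23.1 CPM in controls and at 42.1, 2269 and 100.97 CPM in mutants 1, 2 and 3 (adjusted p = 0.280).

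The haematopoietic progenitor list did not pass (median log2 1.61, adjusted p = 0.337), with 1 member higher and 1 lower of 14, or 3 and 2 adjusted over the list alone. Cd93, a surface protein of early progenitors and endothelium, rose from 31.4 ± 1.95 to 139 ± 60.2 CPM (log2 2.17 ± 0.39, adjusted p = 0.0234). Mecom, a transcription factor of stem cells, fell from 3.27 ± 0.371 to 0.972 ± 0.313 CPM (log2 -1.74 ± 0.38, adjusted p = 0.0378). Among the mast cell, basophil and eosinophil genes 1 of 10 passed, also 1 adjusted over the list alone, and the list did not (adjusted p = 0.988). Its median was 0.86, camera pointed up and fry down. Cma1, a mast cell protease, fell from 0.950 ± 0.315 to 0.152 ± 0.0223 CPM (adjusted p = 0.0215), and Siglecf, an eosinophil lectin, was at 0.405 ± 0.0775 and 1.46 ± 0.932 CPM (adjusted p = 0.0814). Cd93, Mecom and Cma1 no longer passed without any single control, and without mutant 2 the progenitor genes that rose numbered 5 and those that fell 2, against 6 and 3 by DESeq2 with all libraries.

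The endothelium list did not pass (median log2 0.64, adjusted p = 0.145), with 2 members higher and 1 lower of 18, the same counts adjusted over the list alone. Pecam1, an adhesion molecule of endothelium, platelets and leukocytes (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628), fell from 307 ± 13.6 to 132 ± 13.7 CPM (log2 -1.21 ± 0.16, adjusted p = 0.0122). Eng, the co-receptor endoglin of endothelium and erythroid precursors, rose from 96.4 ± 9.43 to 198 ± 51.5 CPM (log2 1.04 ± 0.21, adjusted p = 0.0322), and Egfl7, a secreted endothelial factor, was the other that rose. Cdh5 was at 41.7 ± 2.87 CPM in controls and at 44.1, 42.6 and 164 CPM in mutants 1, 2 and 3 (log2 0.99 ± 0.54, adjusted p = 0.260). Without mutant 2 the endothelium list passed as higher with 7 members higher (adjusted p = 0.0245), and so it did by limma-voom with sample weights (adjusted p = 0.0198, over a range up to 0.784). The 3 endothelial genes no longer passed without any single control, and without mutant 3 neither Eng nor Egfl7 passed and 3 members were lower, while DESeq2 gave 5 higher and 2 lower.

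Pi4ka, the lipid kinase gene named by the screen (ENSMUSG00000041720, chromosome 16, 17280351 to 17406314), was at 119 ± 11.1 CPM in controls and 94.5 ± 12.8 CPM in mutants (log2 -0.32 ± 0.16, adjusted p = 0.238). Its levels in mutants 1, 2 and 3 were 82.9, 92.5 and 108 CPM. The phosphatidylinositol 4-kinase list did not pass (adjusted p = 0.903), with a median of 0.06 against a set test that pointed down, and 1 member rose and 1 fell of 17, the same adjusted over the list alone. Efr3b, which anchors the kinase complex at the plasma membrane, fell from 8.62 ± 0.910 to 1.88 ± 1.13 CPM (log2 -2.21 ± 0.49, adjusted p = 0.0400). Pip5k1b, a kinase that acts on the product of Pi4ka, rose from 12.7 ± 2.59 to 38.7 ± 15.9 CPM (log2 1.62 ± 0.38, adjusted p = 0.0472). The list of leukaemia-associated genes did not pass (adjusted p = 0.988; median 0.05 and a test that pointed down), with 1 higher and 1 lower of 22, the same adjusted over the list alone. Runx1, a regulator of blood formation, rose from 64.8 ± 3.36 to 116 ± 25.7 CPM (log2 0.84 ± 0.18, adjusted p = 0.0375). Ikzf1, a lymphoid transcription factor, fell from 357 ± 29.9 to 203 ± 14.4 CPM (log2 -0.80 ± 0.17, adjusted p = 0.0325). With upper-quartile normalization, which moved the median of all genes by -0.10, both list medians were -0.05 and Pip5k1b and Runx1 no longer passed. Without any single control the genes of these lists no longer passed.

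The remaining lists did not pass their set tests. In the stress erythropoiesis list (adjusted p = 0.389; median -0.36, mean 0.36 and a test that pointed down) 1 member rose and 1 fell of 9, the same adjusted over the list alone. Erfe, the erythroid hormone that lowers hepcidin, rose from 0.338 ± 0.252 to 28.2 ± 29.7 CPM (log2 6.43 ± 1.25, adjusted p = 0.0286), and Epas1, a hypoxia-inducible factor, fell from 131 ± 13.8 to 53.1 ± 13.04 CPM (log2 -1.28 ± 0.25, adjusted p = 0.0281). The interferon response list had 1 of 14 higher, also 1 adjusted over the list alone (adjusted p = 0.503), and passed as higher without mutant 1 with 5 members higher (adjusted p = 0.0269, over a range up to 0.976), while 3 members were lower without mutant 2. Its members Oas1a, an antiviral enzyme, and Ifit2 had adjusted p of 0.0245 and 0.121, with Oas1a rising from 8.60 ± 1.95 to 35.3 ± 14.1 CPM and Ifit2 at 13.9 ± 1.43 and 27.6 ± 11.0 CPM. The immediate early and heat shock list, a sign of tissue handling, had 1 higher and 1 lower of 12, the same adjusted over the list alone (adjusted p = 0.337). Fos rose from 3.11 ± 0.287 to 14.6 ± 5.93 CPM (adjusted p = 0.0256), while Zfp36, which degrades cytokine transcripts, fell from 246 ± 5.84 to 64.0 ± 16.01 CPM (adjusted p = 0.0122). Of the exocrine pancreas list 0 of 5 tested genes passed by edgeR, with 1 at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom (list adjusted p = 0.248). Its most abundant gene Cela1 was at 18.7 ± 4.31 and 32.2 ± 21.3 CPM. The adipose list had 4 tested genes and no set test (median -0.58, mean -0.15). Fabp4, a fatty acid carrier of fat, endothelium and macrophages, rose from 6.52 ± 2.13 to 72.7 ± 66.3 CPM (log2 3.47 ± 0.69, adjusted p = 0.0302), and Pck1 was at 0.318 ± 0.141 and 0.0405 ± 0.0271 CPM (adjusted p = 0.0520), both passing adjusted over the list alone. Erfe, Epas1, Oas1a, Fos, Zfp36 and Fabp4 no longer passed without any single control.

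Among genes past the threshold with no overlap between groups and an average log2 CPM of at least 2, with Xist, Y-linked genes, antigen receptor segments and predicted genes left out, the one that rose most was En2, a homeobox gene of the midbrain (ENSMUSG00000039095, chromosome 5, 28165694 to 28172166), with 15 counts over the 3 controls and 6141, 4392 and 4188 counts in mutants 1, 2 and 3. Its level went from 0.0647 ± 0.0115 to 65.9 ± 15.995 CPM (log2 9.96 ± 0.35, adjusted p = 0.000393). These counts may include reads of the transposon, as described in the closing section. The next 7 by fold change were Ankrd36, C2cd4a, Nts, Myh7b, Saa3, Erfe and Rnf128, with log2 fold changes between 6.38 and 8.35 and adjusted p between 0.0286 and 0.0458. Each of these 7 was uneven among the mutants: Nts, a neuropeptide gene, was at 1.28, 15.9 and 61.8 CPM, and Saa3, an acute phase gene, at 0.933, 48.1 and 12.4 CPM in mutants 1, 2 and 3. Lrg1, a secreted glycoprotein gene (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), rose evenly from 25.3 ± 1.24 to 140.02 ± 6.64 CPM (log2 2.48 ± 0.16, adjusted p = 0.00153). Mt1, a metallothionein gene that binds zinc (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), rose from 37.3 ± 5.41 to 229 ± 46.8 CPM (log2 2.62 ± 0.22, adjusted p = 0.00369). Of the 8 such genes that fell most, Fcer2a, Cr2, Fcmr and Ms4a1 belong to the B-cell list. The others were H2-Ea-ps, a polymorphic class II pseudogene with 16993 counts in controls and 7 in mutants, the interleukin 5 receptor gene Il5ra (18.9 ± 3.93 to 0.0727 ± 0.0808 CPM), the immunoglobulin receptor gene Fcamr (20.1 ± 1.15 to 0.0984 ± 0.0223 CPM) and Dtx1, a Notch pathway gene (312 ± 36.4 to 1.89 ± 0.228 CPM). C57BL/6 mice are known to carry an inactive form of H2-Ea-ps, and the 64.2 to 80.7 CPM of the 3 controls go against that strain label. The 7 counts of the mutants fit the label but do not settle their strain. The class II genes H2-Eb2, H2-Oa and H2-Ob also fell (log2 -5.05, -5.02 and -5.17), though less than H2-Ea-ps (log2 -11.1). A strain difference between the groups at this gene was therefore not excluded, and its fall cannot be read as a change in expression alone.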

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

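The fit with a variance for each group and the fit without X and Y genes were chosen after the data were seen. The counts of genes higher in mutant spleens (995), genes lower in mutant spleens (1351), lists higher (5) and lists lower (6) stayed within 1.5 times their values in 57 comparisons with an alternative and moved further in 19. DESeq2 gave 2841 genes higher and 2809 lower, limma-voom with sample quality weights gave 1842 higher, and the fit with a variance for each group gave 786 lower, and the cause was not tested. A test against a 2-fold change gave 87 higher and 541 lower, as its construction demands more of each gene. With 1 library left out, genes higher ranged from 4 (without control 2) to 2794 (without mutant 2) and genes lower from 119 to 3137. The joint coefficient of variation was 54.1% with all libraries, 62.5% to 62.8% without a control and 42.6% to 48.5% without a mutant. Lists higher ranged from 3 to 7.

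Camera with an estimated correlation left 0 lists higher and 0 lower, with adjusted p of 0.784 (erythroid), 0.597 (neutrophil), 0.210 (B cell) and 0.597 (T cell). Fry left 1 list higher, and gave 0.252 for erythroid and 0.238 for neutrophil genes. With 1 library left out, the adjusted p of the erythroid list ranged from 2.84e-06 (without mutant 1) to 0.257 (without mutant 2) and that of the neutrophil list from 4.14e-12 to 0.0740, again without mutants 1 and 2. The B-cell and T-cell lists passed in every other alternative run. Of the values of the 60 named genes under alternatives, 841 kept their direction and side of the threshold, 151 no longer passed, 16 newly passed and 3 changed direction. The 3 were C1qa at -0.076 and Cela1 at -0.30 with sample quality weights, and C1qa at -1.03 without mutant 2, where leaving out the other libraries gave up to 3.15, and the causes were not tested. No paired analysis was possible because the labels give no replicate numbers shared by mutants and controls. In simulated counts with a joint dispersion per gene for both groups, edgeR found 0% of 2-fold and 10.4% of 4-fold changes. The real coefficient of variation was 72.7% in mutants and 17.1% in controls, so these shares need not hold for the real libraries. Changes of that size may still have been missed.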

Other observations

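The tests on the B-cell list and on haemoglobin were chosen only after the result was seen. Each mutant spleen had transcripts of its own: 351, 309 and 228 genes were at least 4-fold above all other libraries in mutants 1, 2 and 3, against 2, 0 and 5 in the controls. In mutant 1 these included Fcer1a, a chain of the immunoglobulin E receptor of mast cells and basophils, at 169 CPM against 0.352 CPM or less elsewhere, and Rab3b, a GTPase of secretory vesicles, at 1990.2 CPM. Mutant 1 also had progenitor genes at high levels, with Meis1 at 259 CPM, Gata2 at 399 CPM and Mycn at 149 CPM, against control means of 10.1, 13.7 and 2.47 CPM. Hbb-y, an embryonic globin gene, was at 257 CPM in mutant 1, 0.565 CPM in mutant 2, 1.29 CPM in mutant 3 and 0.0566 ± 0.0276 CPM in controls (adjusted p = 0.0724). In mutant 2 the macrophage genes Cbr2 and C3ar1 were at 308 and 177 CPM and the monocyte chemokine gene Ccl12 at 228 CPM, each at 3.57 CPM or less in the other libraries. In mutant 3 the secreted carbonic anhydrase gene Car6 was at 1720 CPM and Dlk1, a Notch-like gene of fetal tissues, at 449 CPM, each at 0.508 CPM or less elsewhere.

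Epo, the gene of the hormone erythropoietin, had 740 counts in mutant 3 and 0 counts in the 5 other libraries. The cytotoxic gene Gzmb was at 807 CPM in mutant 1 and at 7.38 and 0.704 CPM in mutants 2 and 3. The T-cell genes Cd4 and Lat were above their control means of 97.2 and 131 CPM in 1 mutant each, with Cd4 at 197 CPM in mutant 2 and Lat at 559 CPM in mutant 3. Counts assigned to Foxf2, a forkhead transcription factor gene, rose from 2 over the 3 controls to 703, 109 and 489 in mutants 1, 2 and 3 (adjusted p = 0.0151 by edgeR). The ratio was 671, with a 95% exact counting interval of 185 to 5546. Whether these reads came from the Foxf2 gene or from transposon sequence, as is asked for En2 below, was not analysed here. The 78 ribosomal protein genes had a median log2 fold change of 0.41, with library medians of 0.79, -0.40 and 0.58 in mutants 1, 2 and 3.

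En2 had 14721 counts in the mutants and 15 in the controls. The T2/Onc2 transposon is known to carry a splice acceptor derived from mouse engrailed-2, so reads of the transposon may be counted as En2. The other 5 tested genes within 500 kb of En2 went both ways (Insig1 -0.75, Rbm33 -0.56, Paxip1 0.69, Gm10290 2.11 and Dpp6 2.33). Gm10290 was near the floor (0.0874 CPM in controls and 0.379 CPM in mutants), and Dpp6 was high only in mutant 2 (4.81 CPM). The median log2 fold change of the 5 genes, 0.69, stayed within 2-fold, as predicted beforehand for reads of the transposon. A rise of En2 alone would also leave its neighbours unchanged, so the explanation stays open. A midbrain and hindbrain programme was argued against, since 0 of 8 of its genes examined reached 1 CPM in every mutant library, although Gbx2 was at 3.90 CPM in mutant 1 and at 0.713 and 0.104 CPM in mutants 2 and 3. The gene counts hold no reads, so the part of En2 that was read was not analysed here.

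The B-cell list fell in all 3 mutants, of which mutants 1 and 2 differed from the controls in sex. Sex as the whole cause was argued against by mutant 3, which had Y-linked counts and a B-cell median of -6.89. Its Ddx3y and Kdm5d levels lay within the control range. Its Uty and Eif2s3y levels were higher, at 24.1 and 103 CPM against at most 11.9 and 99.6 CPM in controls. Gm47283, annotated on the Y chromosome, fell from 80.9 ± 36.4 CPM in controls to 0.558 ± 0.195 CPM over the 3 mutants. The cause of these differences was not tested. Dilution of every resident cell type by the same factor would lower the B-cell and T-cell lists alike. The difference between their medians was -2.33 on average (SD 1.31, n = 3) and below 0 in all 3 mutants. This cannot decide, since cells gained in a mutant may also transcribe genes of the T-cell list. Cd4 and Lat of that list were above their control means in 1 mutant each. Other lists of resident cells fell less or not at all. In mutants 1, 2 and 3 the endothelium median was 0.22, -0.18 and 1.01. The splenic stroma median was -3.49, -1.10 and -1.49, against -6.56, -6.45 and -6.89 for B cells. These values argue against dilution of all these cell types by the same factor, unless gained cells also transcribe the endothelial and stromal genes. A loss of B cells beyond that of T cells in the mutant genotype stays open as a hypothesis, as do age, litter and genetic background, which were untested. The splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With either direction of a split counted, 1 of 10 gave as many genes as the 995 higher. For the 1351 lower it was also 1 of 10 (highest other 0 by edgeR for both). For lists, 8 gave as many as the 5 higher and 7 as many as the 6 lower (highest other 12 for both). The list counts by camera with a preset correlation therefore did not set the genotype grouping apart from other splits.

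Haemoglobin genes had a lower mean share of counts in the mutants (2.05% against 9.44%) while Tal1 and Tfr2 rose. The medians of 8 late erythroid genes lay below the controls in mutants 1 and 3 (-1.77 and -1.90 in log2) and above them in mutant 2 (1.73), so in 2 of the 3 mutants they were lower together with haemoglobin. They lay above the medians of the 4 haemoglobin genes by 2.71 on average (SD 0.92, n = 3) and in all 3 mutants. Less blood in the mutant pieces stays open for the lower haemoglobin counts, since late transcripts of resident precursors could leave such a difference. Less blood alone would not raise Tal1, Tfr2 or, in mutant 2, the late genes, so it leaves that part of the pattern unexplained. Less blood together with more erythroid precursors and a block late in erythroid maturation stay open as well, and counts from bulk tissue do not separate these.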
